A study of Methylocystis sp. SB2 with 6 samples.

How the data were processed

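RNA was sequenced from 6 cultures of Methylocystis strain SB2, 3 grown on methane and 3 on ethanol, harvested in late exponential phase. Per the labels' protocols, rRNA was reduced with a MICROBExpress kit and libraries were made with a TruSeq mRNA kit; whether the libraries kept strand is not given in the sources used here. Per the submitters' processing notes, BWA, SAMtools 0.1.17 and Cufflinks 2.0.2 were used, with no role stated for each. Per the file headers, the reference was the strain's draft assembly with an annotation from JGI IMG, with 3657 features on 148 contigs; no other build name is given in the sources used here, and coordinates are those of that annotation, counted from 1.

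The deposited data are 2 tables of the whole series. The first is the authors' comparison of the conditions, and its FPKM columns hold 1 value per condition, which the authors' tool made from 3 cultures. Its other columns are the authors' log2 ratio of ethanol over methane, the authors' test score (test statistic), the authors' p-value and q-value, and the call. The second table holds the annotation alone. The test of whether both tables hold one comparison, planned before the data were examined, was therefore not possible; instead, all 3200 rows of the comparison were matched to the annotation by gene ID, and 3194 had the same product name in both. There were 22 genes with 2 rows each, and all rows were kept.

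The authors' log2 column equals the log2 of the ratio of the deposited FPKM within 4e-05 for the rows with both values above 0. The deposited q-values equal Benjamini-Hochberg values over the 2714 tested rows within 5e-07, and the call equals a q-value at or below 0.05 in all rows. The smallest deposited p-value is 5e-05, shared by 401 rows. The authors' tool left 483 rows untested for too few reads and 3 as too deep. Depth per library is unknown. Of the 50 lowest products of FPKM and gene length, 20.0% on methane and 18.0% on ethanol lay within 0.05 of a whole multiple of the lowest, so whole reads could not be recovered. There were 16 rows listed at 0 on methane and 5 on ethanol, none of them a ribosomal protein; folds are not given for these.

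No test across cultures could be run, because the values are pooled per condition. Calls are those of the authors. Fold changes of single genes are plain ratios of the authors' FPKM. For gene lists, log2 ratios of FPKM with a pseudocount of 1 were used, which understates the change of low genes. The 23 lists were fixed before the data were examined and matched by product name, because the tables hold no gene symbols. For each list with at least 3 rows, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn with a fixed seed from the same 10 bins of mean log2 expression. This percentile describes these libraries and is not a p-value. Counts adjusted over the list alone are Benjamini-Hochberg values over the deposited p-values of the list's tested rows. On simulated data (the 3200 ratios shuffled, 200 lists of 10 members), 3.50% of lists with no shift fell outside the 2.5 and 97.5 percentile limits. Shuffling removed any likeness of neighbouring genes and any link of ratio with expression. Real lists that hold neighbouring genes may therefore leave the limits more often than 3.50%. With a log2 shift of 1, 40.5% of lists shifted up and 47.5% of lists shifted down were found, and with a shift of 2, 98.0% and 97.0%, so moderate shifts of small lists can be missed. The requirement that most shifted lists be found was first set at a shift of 1, where it was not met, and was then set at a shift of 2. Some products matched a list by name only (for example isopropylmalate dehydrogenase under malate dehydrogenase). The set of such rows was drawn up after the data were examined, and the counts and medians of the lists they affect are given with and without them; shares include them unless stated.

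The genes named were set by a rule fixed before the data were examined: the 10 largest increases and 10 largest decreases among called rows with at least 10 FPKM in the higher condition and both values above 0, with at most 3 hypothetical proteins per direction; the 5 highest protein-coding rows per condition; of each list the 2 to 4 members with the highest mean, or up to 8 for the lists of methane monooxygenase, methanol dehydrogenase, serine cycle, ethylmalonyl-CoA pathway, TCA cycle and alcohol metabolism; and at most 3 rows listed at 0 in one condition. Within lists, rows that matched by name only were passed over. Alternatives tried were other thresholds, pseudocounts, floors, scalings and denominators. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.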

Results

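Transcripts were measured by RNA sequencing in Methylocystis strain SB2, a facultative methanotroph of the Alphaproteobacteria, that is, a bacterium that oxidises methane and can also grow on some compounds with carbon-carbon bonds. The cultures were harvested in late exponential phase in a mineral medium with nitrate and 10 µM copper, and had either methane or 0.1% (v/v) ethanol as the growth substrate. There were 2 groups of 3 cultures each. The values are the authors' FPKM (fragments per kilobase of gene, scaled by the authors to the fragments mapped), 1 pooled value per condition, so that no spread between cultures and no sequencing depth per library can be given here. Replicate error enters through the authors' own test only, and genes are said below to have risen or fallen where that test called them. The comparison held 3200 rows for 3178 of the 3657 annotated features, of which 3180 rows were protein-coding. The median protein-coding row had 7.32 FPKM on methane and 6.28 FPKM on ethanol. Ribosomal RNA still made up 83.8% of all FPKM on methane and 83.2% on ethanol after the kit-based removal of rRNA, but these shares cannot be compared, since 1 rRNA row too deep to test (SB2_01450) was listed at 0 on methane and at 394293 FPKM on ethanol.

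The series addresses how the transcript pool differs between growth on methane and growth on ethanol. On ethanol, the abundant transcripts of methane monooxygenase and both subunits of methanol dehydrogenase were at a small fraction of their level on methane, and both subunits of a Ni,Fe-hydrogenase, NifH and NifD of nitrogenase and the L subunit of the photosynthetic reaction centre fell too. Of 4 phasins (proteins of the polyhydroxybutyrate granule surface) 3 rose, as did a cold-shock protein and 2 ArsR-type regulators (SB2_01372 and SB2_02194). TCA cycle enzymes and ribosomal proteins were called in both directions. In the authors' deposited table, 1289 of the 2714 tested rows (47.5%) were called at a q-value of 0.05 or less, 645 of them higher and 644 lower on ethanol. The median log2 ratio in the authors' deposited table was 2.05 among rows called higher and -2.14 among those called lower. Over all rows the median log2 ratio of ethanol over methane, with 1 FPKM added to both values, was -0.02. At a stricter q-value of 0.01 the authors' deposited table holds 794 calls. A large ratio did not always bring a call: 43 of the 163 tested rows with an absolute log2 ratio of at least 4 were not called in the authors' deposited table.

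Methane monooxygenase had the lowest median of the fixed lists over all their rows. Particulate methane monooxygenase, the membrane enzyme that oxidises methane to methanol, is annotated in several gene sets on the draft contigs. Subunit C (SB2_03556, contig SB2_101.96, bases 2600 to 3370, minus strand, protein-coding) fell from 3345 to 130 FPKM, a 25.7-fold decrease, with q = 0.00137 in the authors' deposited table. Subunit A fell 16.5-fold from 508 to 30.8 FPKM in the same set (SB2_03555, bases 1566 to 2324), and 16.4-fold from 575 to 35.1 FPKM in the set on contig SB2_12.32 (SB2_02329, bases 40104 to 40862). Subunit B fell 12.5-fold (SB2_03554, 493 to 39.4 FPKM) and 10.9-fold (SB2_02328, 496 to 45.3 FPKM). The q-value of these subunit A and B genes was 0.000338, the smallest that occurs in the authors' deposited table. Subunits A and B of these sets had the same product names and similar values, and reads that match both copies cannot be assigned from the table, so the level of each copy is uncertain. A further set on contig SB2_120.51 had low values on both substrates: 4.78 and 2.18 FPKM for subunit C (SB2_02930), 6.21 and 2.65 FPKM for subunit B (SB2_02931), 2.73 and 2.72 FPKM for subunit A (SB2_02932), on methane and ethanol respectively. None of that set was called in the authors' deposited table. Of the 9 measured rows of the list, 0 were called higher and 5 lower in the authors' deposited table, and 6 were lower when its p-values were adjusted over the list alone. The list's median log2 ratio was -3.42, below all 10000 random lists of matched expression (percentile 0). The list took 3.92% of the protein-coding FPKM on methane and 0.220% on ethanol.

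Methanol dehydrogenase, the periplasmic enzyme that uses the cofactor pyrroloquinoline quinone (PQQ) for the next step, fell further. Its small subunit (SB2_00609, contig SB2_7.5, bases 61314 to 61604) fell 108-fold from 479 to 4.43 FPKM, and its large subunit (SB2_00612, bases 63306 to 65180) fell 48.4-fold from 190 to 3.92 FPKM. In the authors' deposited table their q-values were 0.00204 and 0.000338. A PQQ-dependent dehydrogenase of the methanol/ethanol family on another contig (SB2_03432) had 33.9 FPKM on methane and 25.1 FPKM on ethanol and was not called in the authors' deposited table (q = 0.473). The genes for synthesis of the cofactor were called in both directions: proteins B (SB2_01276, 17.7 to 3.72 FPKM) and C (SB2_01277, 10.3 to 2.40 FPKM) fell, and the adjacent fused PqqE/PqqD gene (SB2_01278, 12.5 to 47.9 FPKM) rose. Of the 9 rows matched by the fixed list, 2 were higher and 4 lower in the authors' deposited table, with the same counts adjusted over the list alone. The median of the 9 was -0.42 (percentile 18.2), but 3 of them matched by name only, and the remaining 6 had a median of -1.86 (percentile 1.93), with 1 higher and 4 lower in the authors' deposited table, the same adjusted over the list alone.

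**Figure D1:**
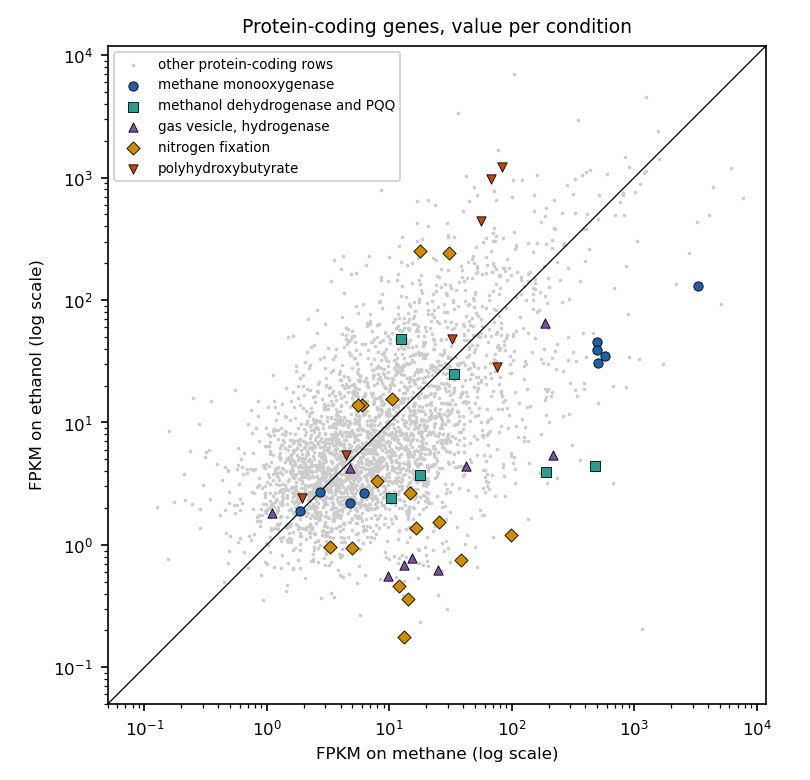
Authors' FPKM per protein-coding row on methane (horizontal, log scale) against ethanol (vertical, log scale); the line marks equal values, and 5 lists are marked. The 5 abundant methane monooxygenase rows lie far below the line, down to 30.8 FPKM on ethanol, while 3 phasin rows lie above it; 15 rows listed at 0 in a condition are not drawn.

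Of the steps after methanol, 4 genes of formaldehyde oxidation fell, while formate dehydrogenase subunits went both ways. A formaldehyde-activating enzyme (SB2_03645), which condenses formaldehyde with tetrahydromethanopterin, fell 21.5-fold from 173 to 8.04 FPKM, and a second one (SB2_03426) fell 3.71-fold from 26.7 to 7.2 FPKM. Methenyltetrahydromethanopterin cyclohydrolase (SB2_02641, 18.0 to 7.93 FPKM) and subunit A of formylmethanofuran dehydrogenase (SB2_01314, 7.14 to 2.01 FPKM) fell as well. In this list of 7 rows 0 were higher and 4 lower in the authors' deposited table, again 4 adjusted over the list alone, and the median was -1.09 (percentile 3.74). Formate dehydrogenase, which oxidises formate to carbon dioxide, did not move as a unit: its alpha subunit (SB2_01356) fell from 54.0 to 13.1 FPKM and its gamma subunit (SB2_01358) rose from 23.9 to 119 FPKM. The beta subunit (SB2_01357) between them, at 18.9 and 35.7 FPKM, was not called. That list of 4 had 1 row higher and 1 lower in the authors' deposited table, over all rows and adjusted over the list alone, and a median of 0.66 (percentile 69.4).

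In the serine cycle, by which methylotrophs of this group assimilate formaldehyde carbon, the called enzymes were lower on ethanol. Serine-glyoxylate aminotransferase (SB2_01774) fell 5.62-fold from 14.5 to 2.57 FPKM, malyl-CoA lyase (SB2_01767) 6.08-fold from 9.01 to 1.48 FPKM, phosphoenolpyruvate carboxylase (SB2_03343) 3.53-fold from 11.8 to 3.35 FPKM and malate dehydrogenase (SB2_01837) 2.94-fold from 20.1 to 6.84 FPKM. Serine hydroxymethyltransferase (SB2_01632, 12.2 and 15.1 FPKM), enolase (SB2_01712, 6.06 and 11.8 FPKM), formate-tetrahydrofolate ligase (SB2_01775, 7.46 and 8.76 FPKM) and the small subunit of malate thiokinase (SB2_01769, 6.48 and 3.72 FPKM) were not called in the authors' deposited table. The fixed list matched 18 rows, 3 higher and 6 lower in the authors' deposited table (4 and 6 adjusted over the list alone), with a median of -0.58 (percentile 5.71). The 3 higher rows, 2 of them phosphoglycerate kinase and phosphoglycerate dehydrogenase and the third isopropylmalate dehydrogenase, belong to other pathways. Without name-only matches, 13 rows remained with 0 higher and 6 lower in the authors' deposited table and a median of -0.79 (percentile 3.89). With tested rows only, name-only matches included, 16 rows of this list had a median of -0.16 (percentile 49.0). In the ethylmalonyl-CoA pathway, which regenerates glyoxylate from acetyl-CoA, 1 of 11 rows was higher and 2 lower in the authors' deposited table (0 and 2 adjusted over the list alone), and the median was -0.37 (percentile 36.1). An acetyl-CoA acetyltransferase (SB2_00962) rose from 50.1 to 113 FPKM, while another (SB2_02019) fell from 21.5 to 8.04 FPKM and an acetyl/propionyl-CoA carboxylase (SB2_00958) fell from 19.1 to 5.07 FPKM. Crotonyl-CoA carboxylase/reductase (SB2_02675, 13.1 and 15.8 FPKM), ethylmalonyl-CoA mutase (SB2_02672, 11.5 and 13.9 FPKM), methylsuccinyl-CoA dehydrogenase (SB2_02681, 13.1 and 6.17 FPKM), methylmalonyl-CoA epimerase (SB2_01803, 6.22 and 12.8 FPKM) and a further acetyltransferase (SB2_03524, 11.3 and 8.51 FPKM) were not called in the authors' deposited table.

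Members of the TCA cycle went both ways. The alpha subunit of succinyl-CoA synthetase (SB2_01040, contig SB2_13.10, bases 42178 to 43062) rose 6.91-fold from 101 to 697 FPKM, and the E1 component of 2-oxoglutarate dehydrogenase beside it (SB2_01041) rose 2.90-fold from 33.4 to 96.7 FPKM. Succinate dehydrogenase subunits C (SB2_00324, 10.7 to 65.6 FPKM) and D (SB2_00323, 11.0 to 27.8 FPKM) rose too. Aconitate hydratase (SB2_02602) fell from 21.4 to 5.67 FPKM, and 2 genes annotated as pyruvate/2-oxoglutarate dehydrogenase components fell 8.71-fold (SB2_00965, 81.6 to 9.37 FPKM) and 11.0-fold (SB2_00964, 59.9 to 5.45 FPKM). A further gene with that annotation (SB2_01457) stood at 43.6 and 57.2 FPKM and was not called. The annotation also names pyruvate dehydrogenase, so the place of these genes in the TCA cycle is uncertain. The fixed list matched 19 rows, 6 higher and 5 lower in the authors' deposited table (6 and 6 adjusted over the list alone), with a median of 0.28 (percentile 78.1). Without 2 name-only matches, 5 were higher and 5 lower in the authors' deposited table (5 and 6 adjusted over the list alone), with a median of 0.28 (percentile 76.0). Neither isocitrate lyase nor malate synthase, the enzymes of the glyoxylate shunt, was found by product name, since the 2 matches of that list are isopropylmalate synthases, 1 of them higher in the authors' deposited table, both over all rows and adjusted over the list alone. Among enzymes of alcohol, aldehyde and acetate metabolism, an NAD-dependent aldehyde dehydrogenase (SB2_01328) rose 4.40-fold from 22.2 to 97.8 FPKM and a short-chain alcohol dehydrogenase of unknown specificity (SB2_01919) rose 6.04-fold to 8.44 FPKM. Another aldehyde dehydrogenase (SB2_01688, 86.3 and 46.1 FPKM), phosphotransacetylase (SB2_00467, 3.73 and 7.86 FPKM), a zinc-binding alcohol dehydrogenase (SB2_01210, 3.71 and 4.49 FPKM) and acyl-CoA synthetases SB2_01245 (18.3 and 27.1 FPKM) and SB2_01013 (7.59 and 7.03 FPKM) were not called in the authors' deposited table. The acyl-CoA synthetase SB2_00528 fell from 24.3 to 3.97 FPKM. That list matched 24 rows, 4 higher and 5 lower in the authors' deposited table (3 and 5 adjusted over the list alone), with a median of 0.25 (percentile 83.6). Of these, 14 matched by family name only, and the other 10 held 2 higher and 1 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.36 (percentile 77.4).

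Of 4 phasins 3 rose, and NifH and NifD of nitrogenase fell, and the lists that hold them had calls in both directions. The phasins SB2_00251 and SB2_02419 rose 14.6-fold (82.7 to 1210 FPKM) and 14.4-fold (from 67.5 FPKM), another phasin (SB2_00250) rose 7.80-fold (56.3 to 439 FPKM), and the repressor PhaR (SB2_03525) fell 2.71-fold (76.5 to 28.2 FPKM). The polyhydroxybutyrate list of 7 had 3 rows higher and 1 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.55 (percentile 67.6). Its share of protein-coding FPKM was 0.232% on methane and 2.05% on ethanol, most of the latter from the phasins that rose. The nitrogenase iron protein NifH (SB2_00559, contig SB2_7.5, bases 17798 to 18685) fell 82.7-fold from 99.3 to 1.20 FPKM, and the NifD subunit (SB2_03581) fell 50.4-fold from 38.2 to 0.757 FPKM. Both ethanol values lie at or near the low end, where percentile 5 of protein-coding rows was 1.18 FPKM, so the size of these folds is uncertain. The NifU-type iron-sulfur scaffold proteins SB2_03539 (17.7 to 252 FPKM) and SB2_02495 (30.6 to 243 FPKM), which also serve enzymes other than nitrogenase, rose. The nitrogen fixation list of 17 rows had 4 higher and 6 lower in the authors' deposited table (4 and 7 adjusted over the list alone), with a median of -1.60 (percentile 0.01), or -1.86 (percentile 0) and the same counts without 1 name-only match. With a floor of 10 FPKM on the mean, 6 rows remained, with a median of -1.43 (percentile 16.5). In nitrate and ammonia assimilation, a nitrate/nitrite transporter (SB2_02671) rose from 7.27 to 45.2 FPKM, the beta subunit of assimilatory nitrate reductase (SB2_00689) fell from 38.4 to 8.40 FPKM, and an ammonium transporter (SB2_03317, 22.8 and 47.7 FPKM) was not called. The 25 matched rows held 6 higher and 6 lower in the authors' deposited table, the same adjusted over the list alone, and a median of -0.30 (percentile 21.0). Without 3 name-only matches the median was -0.80 (percentile 2.42), with 4 higher and 6 lower in the authors' deposited table, the same adjusted over the list alone.

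Of the hydrogenase genes, those called were lower on ethanol. The large subunit of the Ni,Fe-hydrogenase (SB2_02008, contig SB2_24.25, bases 46556 to 48376) fell 39.5-fold from 216 to 5.47 FPKM, its small subunit (SB2_02009) 2.88-fold from 186 to 64.6 FPKM and the maturation protein HypF (SB2_02001) 9.63-fold from 42.4 to 4.40 FPKM. A maturation protease (SB2_02003) with 24.9 and 0.620 FPKM was not called, nor were the subunits of a further hydrogenase, SB2_00499 (4.80 and 4.27 FPKM) and SB2_00500 (1.11 and 1.83 FPKM), which were picked out after their values were seen. The 15 matched rows of the gas vesicle and hydrogenase list held 0 higher and 8 lower in the authors' deposited table, again 8 adjusted over the list alone, with a median of -2.79 (percentile 0). Of those rows 6 matched by name only, among them both methanol dehydrogenase subunits, and the other 9 held 4 lower in the authors' deposited table with a median of -3.01 (percentile 0.01). Cobalamin biosynthesis was the 1 list above percentile 97.5: 10 of 22 rows were higher and 4 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.97 (percentile 99.9). Cobaltochelatase subunits CobS (SB2_02797, 11.7 to 61.1 FPKM) and CobT (SB2_02795, 12.7 to 55.5 FPKM) rose, and a predicted cobalamin-binding protein (SB2_00817, 33.2 to 4.74 FPKM) fell. That gene and a gene annotated as a cobaltochelatase CobN subunit (SB2_00806, 24.0-fold lower), another of the list's 4 lower rows, lie within a photosynthesis gene cluster on contig SB2_5.7. SB2_00806 lies between protochlorophyllide reductase subunits L and B (SB2_00805 and SB2_00807), so its part in cobalamin synthesis is uncertain. With a floor of 10 FPKM on the mean, 5 rows of the cobalamin list remained and the median of 2.04 lay at percentile 95.6.

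**Figure D2:**
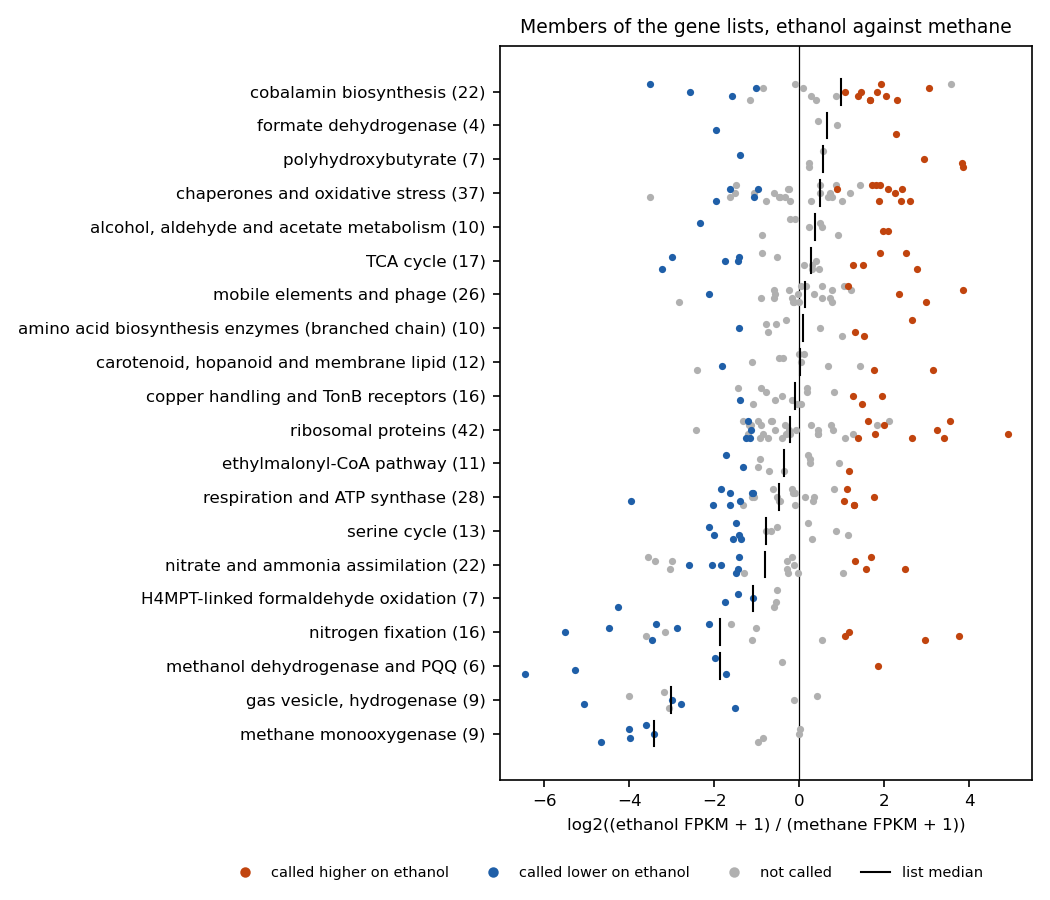
Log2 ratio of ethanol over methane FPKM, with 1 added to each, for every member of 20 lists, without name-only matches; colours show the authors' calls, black ticks the list medians, and numbers in parentheses the members. Medians run from -3.42 for methane monooxygenase to 0.97 for cobalamin biosynthesis, and most lists hold members on both sides of 0.

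Most other lists held calls in both directions, and those with at least 3 rows had medians inside the 2.5 to 97.5 percentile limits. Ribosomal proteins had 11 of 45 rows higher and 4 lower in the authors' deposited table, the same adjusted over the list alone, with a median of -0.08 (percentile 49.4). Without 3 enzymes that modify ribosomal proteins, 9 were higher and 4 lower in the authors' deposited table, the same adjusted over the list alone, with a median of -0.22 (percentile 29.5). L12 (SB2_00472) rose 31.2-fold from 20.8 to 651 FPKM, L10 (SB2_00471) 10.7-fold from 72.1 to 772 FPKM and S13 (SB2_03261) 9.66-fold from 33.8 to 326 FPKM, while S2 (SB2_03087) with 70.5 and 118 FPKM was not called. Chaperones and oxidative stress proteins had 10 of 37 rows higher and 4 lower in the authors' deposited table (9 and 3 adjusted over the list alone), with a median of 0.49 (percentile 93.9). A small heat shock protein (SB2_01102) rose 3.65-fold from 1255 to 4580 FPKM and a DnaJ-class chaperone (SB2_02798) 4.31-fold from 70.5 to 304 FPKM, while Hsp20 (SB2_01309, 1125 and 885 FPKM) and DnaK (SB2_01669, 149 and 247 FPKM) were not called. Respiration and ATP synthase had 5 of 28 rows higher and 8 lower in the authors' deposited table, the same adjusted over the list alone, with a median of -0.47 (percentile 5.63). Of 2 iron-sulfur subunits of ubiquinol-cytochrome c reductase, SB2_02255 rose from 69.0 to 169 FPKM and SB2_02959 fell from 84.9 to 4.54 FPKM. Copper handling and TonB receptors had 3 of 22 rows higher and 4 lower in the authors' deposited table, the same adjusted over the list alone, with a median of -0.36 (percentile 15.9). Without 6 name-only matches, respiratory oxidase genes, 3 of 16 were higher and 1 lower in the authors' deposited table (1 and 0 adjusted over the list alone), with a median of -0.11 (percentile 36.6). A multicopper oxidase (SB2_02012) rose from 20.9 to 83.3 FPKM, and the CopC homologs SB2_02326 (183 and 188 FPKM) and SB2_00413 (65.1 and 57.7 FPKM) were not called. Carotenoid, hopanoid and membrane lipid genes had 2 of 12 rows higher and 1 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.01 (percentile 56.5). A phytoene dehydrogenase-type gene (SB2_01777) rose from 8.77 to 85.7 FPKM, and the hopanoid-associated sugar epimerase SB2_02859 had 14.0 and 22.9 FPKM without a call. Branched-chain amino acid synthesis had 3 of 10 rows higher and 1 lower in the authors' deposited table, the same adjusted over the list alone, with a median of 0.09 (percentile 58.7). Its most abundant members, acetolactate synthase (SB2_02688, 29.6 and 59.8 FPKM) and an isopropylmalate synthase (SB2_02468, 48.8 and 29.0 FPKM), were not called. Mobile elements and phage had 5 of 28 rows higher and 1 lower in the authors' deposited table (3 and 1 adjusted over the list alone), with a median of 0.12 (percentile 60.1). Without 2 name-only matches, 4 were higher and 1 lower in the authors' deposited table (3 and 1 adjusted over the list alone), with a median of 0.12 (percentile 57.5). Its most abundant members, both annotated as a bacteriophage replication protein on contig SB2_49.79, had 815 and 744 FPKM (SB2_03423) and, on methane, 812 FPKM (SB2_03420) and were not called. Both may be control phage DNA added at sequencing and not transcripts of the strain, as set out in the last paragraph. A transposase (SB2_03534, 13.3 to 72.0 FPKM) and a phage tail protein (SB2_02714, 4.12 to 72.9 FPKM) rose. Flagella and chemotaxis had only 2 rows, 1 of them lower in the authors' deposited table, also when adjusted over the list alone. The structural RNA list matched 32 rows, 18 of them protein-coding genes such as rRNA methylases, with 4 higher and 1 lower in the authors' deposited table (3 and 1 adjusted over the list alone) and a median of 0.24 (percentile 59.5). By annotated feature type instead, 20 rows were structural RNA, with 4 higher and 0 lower in the authors' deposited table, the same adjusted over the list alone, and a median of 0.09 (percentile 29.9). The row with the highest value on methane (SB2_03654, a small-subunit ribosomal RNA fragment) had 224157 FPKM on methane and 173022 FPKM on ethanol and was not called.

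The largest single changes fell partly outside these lists. Among called rows with at least 10 FPKM in the higher condition, an ArsR family regulator (SB2_01372, contig SB2_58.14, bases 61996 to 62361) rose 93.8-fold from 8.51 to 798 FPKM. A cold-shock DNA-binding protein (SB2_02534, contig SB2_75.38, bases 8187 to 8399) rose 66.7-fold from 105 to 7028 FPKM, the highest protein-coding value on ethanol. A second ArsR regulator (SB2_02194) rose 54.1-fold from 4.19 to 227 FPKM, a hemolysin-like CBS domain protein (SB2_01044) 44.2-fold from 4.06 to 180 FPKM, a thiazole biosynthesis enzyme (SB2_01917) 38.1-fold from 16.8 to 639 FPKM, a transmembrane sensor domain protein (SB2_01609) 33.7-fold from 4.83 to 163 FPKM and a protein of unknown function (SB2_02165) 33.4-fold from 1.5 FPKM. Hypothetical proteins SB2_00887 (36.5 to 3368 FPKM), SB2_00096 (3.52 to 213 FPKM) and SB2_02536 (6.79 to 227 FPKM) were also among the 10 that rose most. In the other direction, an antenna complex subunit of the photosynthetic apparatus (SB2_00830, contig SB2_5.7, bases 87225 to 87422) fell 211-fold from 670 to 3.18 FPKM, with q = 0.00924 in the authors' deposited table. The adjacent antenna subunit (SB2_00831), named after its values were seen, had 1153 and 0.207 FPKM and was not called in the authors' deposited table (q = 0.111). With at most 3 hypothetical proteins taken per direction, which left out SB2_02005 and SB2_01478, the 10 decreases named held, next to methanol dehydrogenase and nitrogenase, a hemerythrin domain protein (SB2_00174, 60.4-fold, 195 to 3.23 FPKM), the reaction center L subunit (SB2_00829, 52.1-fold, 50.2 to 0.965 FPKM) and hypothetical proteins SB2_01743 (135 to 1.62 FPKM), SB2_01827 (358 to 4.92 FPKM) and SB2_02958 (1709 to 29.8 FPKM). As for nitrogenase, the ethanol value of the L subunit is near the floor (percentile 5 of protein-coding rows, 1.18 FPKM), so its fold and rank are uncertain.

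The most abundant protein-coding transcripts differed between the conditions. On methane, the 5 highest rows had no assigned function, and all 5 fell: SB2_03086 (7817 to 680 FPKM), SB2_02819 (6212 to 1208 FPKM), SB2_01478 (5088 to 92.6 FPKM), SB2_00583 (5.18-fold, from 4365 FPKM) and SB2_00083 (4098 to 492 FPKM). On ethanol, the cold-shock protein was followed by the small heat shock protein SB2_01102, by SB2_00887, by an uncharacterized small protein that rose from 347 to 2937 FPKM (SB2_01043) and by a stress-induced repeat protein that was not called (SB2_02401, 1576 and 2416 FPKM). Listed at 0 in one condition with at least 10 FPKM in the other were 5 tested rows of the authors' deposited table. Among them, an indolepyruvate ferredoxin oxidoreductase (SB2_00570) had 38.7 FPKM on methane and was listed at 0 on ethanol. A hypothetical protein (SB2_01254, 31.1 FPKM) and an XRE family regulator (SB2_01902, 27.2 FPKM) on ethanol were listed at 0 on methane.

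Shares of the transcript pool depended on whether structural RNA was counted. All FPKM summed to 1023139 on methane and 1467010 on ethanol, and a ribosomal RNA row (SB2_01450) listed at 0 on methane and at 394293 FPKM on ethanol, which the authors' tool had left untested as too deep, accounts for most of the gap. Protein-coding rows alone summed to 138748 and 131834 FPKM, a ratio of 0.950. Of protein-coding FPKM, ribosomal proteins took 0.565% on methane and 1.99% on ethanol, chaperones and oxidative stress proteins 2.38% and 5.55%, the TCA cycle 0.311% and 0.791%, and the hydrogenase list without name-only matches 0.370% and 0.0632%. Of all FPKM, methane monooxygenase took 0.531% and 0.0198%, and the polyhydroxybutyrate list 0.0315% and 0.184%. The differences in the TCA cycle, chaperone, ribosomal protein and polyhydroxybutyrate shares come mostly from few abundant rows that rose. These are the alpha subunit of succinyl-CoA synthetase, the small heat shock protein SB2_01102, ribosomal proteins L12, L10 and S13, and the phasins that rose. Such shares do not show that whole lists rose: 30 of 45 ribosomal protein rows were not called, and the list's median was -0.08.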

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

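No paired analysis was possible because the deposited values are pooled over the 3 cultures of each condition. For the same reason the planned replicate block, leaving out each replicate and the DESeq2 alternative were not run, and the alternative with the other deposited table was not run because that table is an annotation. Depth per library is unknown, so what low values can show is limited only as far as the authors' test takes it into account. Added after seeing the data were leaving out name-only matches, using tested rows only, centring on the phage-like contig, and leaving out the 3 rows too deep to test. In the authors' deposited table, 794 rows had a q-value of 0.01 or less, 403 higher and 391 lower. With Bonferroni over the tested rows 0 were called, 0 higher and 0 lower, because the smallest p-value in the authors' deposited table, 5e-05, times 2714 tests is above 0.05. The other 4 alternatives moved these counts by less than 1.5 times, but only the floor of 10 FPKM, which left 1015 calls, could have moved them much. Recomputed Benjamini-Hochberg values equal the deposited q-values. The smallest absolute log2 ratio among called rows was 0.965, close to the cut at 1, and 1285 of the 1289 called rows were protein-coding. Under the alternatives, list medians stayed on their side of the percentile limits in 224 cases, passed a limit in 5 and no longer passed it in 2. Centring on the median of all rows, ribosomal proteins or the phage-like contig moved a list and its random lists alike, so percentiles could not change. These cases, and the name-only alternative for lists without such matches, were fixed in advance and are among the 224. With name-only matches left out, the medians of methanol dehydrogenase and PQQ (-1.86, percentile 1.93) and of nitrate and ammonia assimilation (-0.80, percentile 2.42) passed the lower limit, which 5 lists then passed in place of 3; the members removed are the cause. Methanol dehydrogenase and PQQ also passed it with tested rows only (-1.73), and tetrahydromethanopterin-linked formaldehyde oxidation with a pseudocount of 10 (-0.51). With a mean of at least 10 FPKM, polyhydroxybutyrate passed the upper limit (2.94), and nitrogen fixation (-1.43) and cobalamin biosynthesis (2.04) no longer passed theirs, with 6 and 5 members left. Among lists inside the limits, the median changed sign with that floor for the serine cycle (0.29), the ethylmalonyl-CoA pathway (0.25), alcohol metabolism (-0.89) and ribosomal proteins (0.90), and under 1 scaling each for ribosomal proteins (0.08) and branched-chain synthesis (-0.01), and under 1 scaling and with tested rows only for the carotenoid list (-0.10 and -0.01). For these changes the cause was not tested. Scaling moved the median of all rows by at most 0.1 on the log2 scale, except centring on the phage-like contig, which moved it by 0.16. Shares of all FPKM were given as ethanol over methane. Without structural RNA in the denominator, whose sum differs between the conditions, the ratio turned above 1 for the ethylmalonyl-CoA pathway (1.25), alcohol metabolism (1.09), copper handling (1.08), mobile elements (1.06) and branched-chain synthesis (1.31). Phage replication rows of contig SB2_49.79, which may be control phage DNA, hold 812 and 815 of the mobile elements list's 1791 FPKM on methane. The ratio moved without turning for methane monooxygenase (0.0563), methanol dehydrogenase (0.139), formaldehyde oxidation (0.142), formate dehydrogenase (1.81), the serine cycle (0.975), the TCA cycle (2.54), polyhydroxybutyrate (8.84), nitrogen fixation (1.81), nitrate and ammonia (0.776), respiration (0.942), ribosomal proteins (3.53), chaperones (2.33), cobalamin (1.73), hydrogenase with name-only matches (0.0944) and carotenoids (1.89). The nitrogen fixation ratio above 1 came from the NifU-type proteins SB2_03539 and SB2_02495, which rose, while NifH and NifD fell. As in the shares above, few abundant rows led the ratios of the TCA cycle, polyhydroxybutyrate, ribosomal proteins and chaperones. With FPKM times gene length, formate dehydrogenase (0.507) and nitrogen fixation (0.638) turned below 1, as did cobalamin (0.814, from 1.15), and methanol dehydrogenase moved to 0.150; the weight given to long genes is the only change in that alternative. Leaving out the 3 rows too deep to test turned the ratio above 1 for the ethylmalonyl-CoA pathway (1.13, from 0.827) and branched-chain synthesis (1.19, from 0.871).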

Other observations

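All gene groups and tests of this part were chosen after the results were seen, so the percentiles of these groups describe them and are no evidence for them. All 6 genes of glycine cleavage and glycine oxidase were called higher in the authors' deposited table, with a median log2 ratio of 1.60 (percentile 94.8 among random lists, inside the limits used for the fixed lists). The aminomethyltransferase GcvT (SB2_01087) rose from 23.8 to 594 FPKM and glycine oxidase (SB2_01915), which supplies the glycine-derived part of the thiazole ring of thiamine, from 48.8 to 832 FPKM. Of 8 genes of thiamine and thiazole synthesis, 5 were called higher and 0 lower in the authors' deposited table (median 2.14, percentile 100), among them the sulfur carrier ThiS (SB2_01916, 52.4 to 717 FPKM). Glycine oxidase and the called genes SB2_01916, SB2_01917 and SB2_01918 are consecutive on the same strand of contig SB2_88.24 (bases 6110 to 9461). The glycine and thiamine groups are therefore not independent. Of 5 ArsR family regulators, 4 were called higher in the authors' deposited table (median 4.58, percentile 100), and of 4 methionine sulfoxide reductases, which repair oxidised methionine, 3 were (median 3.37, percentile 99.8), for example SB2_00731 (16.8 to 306 FPKM). Aldolase, transketolase, phosphoribulokinase and related steps of sugar phosphate metabolism had 4 of 5 genes called higher in the authors' deposited table (median 1.62, percentile 92.0, inside the limits), with transketolase (SB2_00762) at 31.6 and 133 FPKM. All of that group but SB2_01909 are consecutive genes on the same strand of contig SB2_5.7 (SB2_00760 to SB2_00763, bases 995 to 5671). Adaptor and outer membrane subunits of RND-type efflux pumps had 6 of 15 called higher and 0 lower in the authors' deposited table (median 0.72, percentile 95.2, inside the limits). Of 6 RNA features without a product name, 4 were called higher in the authors' deposited table, SB2_00122 with 9563 FPKM on methane and 82759 FPKM on ethanol.

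A photosynthesis gene cluster of 49.8 kb on contig SB2_5.7 (bases 48560 to 98408) had 23 of 44 rows called lower and 2 higher in the authors' deposited table, with a median log2 ratio of -2.67, below the lowest median of 694 windows of as many neighbouring rows elsewhere (-1.13). A contig from another organism in the methane cultures is argued against by the 30 other rows of the contig, whose median was 0.02. The scalings tried shift all ratios alike, upward by at most 0.16, so the cluster's median was bound to stay low, at most -2.51. None of these scalings is large enough to account for the cluster, but they are no test of it. Of 2 genes annotated as PpsR, a regulator of such clusters, SB2_00820 rose from 9.27 to 54.0 FPKM and SB2_00810 (20.5 and 36.1 FPKM) was not called. A lower oxygen supply in the methane cultures may account for the cluster. Genes of nitrogen fixation and hydrogenase are often also repressed by oxygen, and their lists had medians of -1.86 or lower without name-only matches. The nitrogen fixation median was -1.60 with these matches, and -1.43 at percentile 16.5 with a mean of at least 10 FPKM. The nitrogen fixation list also went both ways, with 4 rows called higher and 6 lower in the authors' deposited table. Oxygen and substrate cannot be told apart, because methane was supplied mixed with air, each substrate had 1 culture condition and no oxygen measurement was used here.

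Closely spaced genes of the same strand changed together: across 847 neighbouring pairs under 50 bases apart, Pearson's r of the log2 ratios was 0.68 (bootstrap interval 0.64 to 0.73), across genes, which are not independent replicates. A trend along whole regions is argued against by r = 0.14 for 248 same-strand pairs at least 200 bases apart. Reads counted for a neighbour whatever the strand are argued against as the whole cause by r = 0.42 for 295 opposite-strand pairs under 50 bases apart, but that value is above the 0.14 of opposite-strand pairs at least 200 bases apart, so a part may remain. Shared transcripts may account for the rest, which was not tested. Of 176 close same-strand pairs with both genes called in the authors' deposited table, 11 were called in opposite directions, among them the E1 and E2 genes of 2-oxoglutarate dehydrogenase (SB2_01041, 1.54, and SB2_01042, -1.70).

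All 7 rows of contig SB2_49.79, annotated with a microvirus capsid and pilot protein, had 510 to 1594 FPKM on methane and 457 to 1430 FPKM on ethanol, with 0 called in the authors' deposited table. Their log2 ratios spanned 0.14, from -0.27 to -0.13, while the narrowest of 2547 runs of as many neighbouring rows elsewhere spanned 0.57. The replication gene is annotated 2 times, 5386 bases apart, as on a circular genome assembled past its start. These rows may be control phage DNA added at sequencing and not transcripts of the strain. A phage carried by the cultures at a similar level was not tested.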
